A study of Mus musculus with 24 samples.

How the data were processed

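Lung RNA of male C57BL/6J mice was measured by RNA sequencing in 24 libraries, made per the labels from total RNA with a stranded mRNA kit. Groups were taken from the sample titles: young sham, young 1 h, young 1 day, old sham, old 1 h and old 1 day, with 4 libraries each. Young mice were 8 to 12 weeks old and old mice 22 to 24 months. In the reperfused groups the left hilum was clamped for 60 min and then released for 1 h or 1 day. The time after the sham operation at which those lungs were taken is not stated. The labels give no batch, date or lane.

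The deposited table lists 129299 RefSeq transcripts of 45777 genes on mm10/GRCm38. It gives a read count, an FPKM and a TPM for each library. HISAT2 and StringTie made the values per the submitters' processing notes, which give no versions. The deposited read counts are expected counts, that is, estimates per transcript and not tallies of reads: 98.34% to 98.92% of the values under 50 in each library equalled FPKM times transcript length times 1 constant, rounded up. The authors scaled the FPKM by transcript length and library total, and the deposited FPKM served only for that check. TPM values are deposited as well, scaled by the authors to a common sum, and were used in an alternative. Rounding up every transcript adds at most 1 count per transcript, which matters most for genes with few reads.

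Counts of the transcripts of each gene symbol were summed. Genes were kept by the filterByExpr rule of edgeR 4.0.16 (minimum count 10), which left 19690. Library factors were computed by TMM and ranged from 0.8805 to 1.0917. A quasi-likelihood model with 6 group means was fitted to all 24 libraries (glmQLFit, robust), and contrasts were tested by the quasi-likelihood F test in R 4.3.3. Benjamini-Hochberg adjustment was made over all genes within a comparison, and an adjusted p under 0.05 counted as changed. All tests were two-sided. The biological coefficient of variation was 23.2%. The standard error (SE) of a log2 change is its absolute value over the square root of F. Errors of CPM (counts scaled by the TMM-adjusted library total) are standard deviations (SD) over 4 libraries. Totals were 27850677 to 44504824 estimated reads. The labels do not state that libraries are separate animals, so p-values measure the spread between samples.

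Each age was compared with its own sham group at 1 h and 1 day (4 comparisons). Old was compared with young in sham, 1 h and 1 day lungs (3 comparisons). The difference between ages in the change from sham was tested at 1 h and at 1 day as an interaction (2 comparisons). The comparisons of 1 h and 1 day share their sham libraries and were not correlated with each other.

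Lists of genes were fixed before the data were examined, as were the comparisons, tests, thresholds, naming rule and the first set of alternatives. The 31 lists held immediate early genes, inflammatory cytokines, chemokines and NF-kB targets, endothelial activation and coagulation, neutrophil, monocyte and recruited macrophage, alveolar macrophage, alveolar type 2, alveolar type 1, endothelial, club and secretory airway, ciliated cell, B cell, plasma cell, and T and NK cell markers, MHC class II and antigen presentation, interferon-stimulated genes, hypoxia-inducible genes, NRF2 targets and metallothioneins, heat shock proteins, ER stress and integrated stress response, p53 targets, senescence and secretory phenotype genes, cell cycle genes, extracellular matrix and fibroblast genes, acute-phase and complement genes, circadian clock genes, glucocorticoid-induced genes, oxidative phosphorylation genes, red cell and platelet genes, cardiac muscle genes, and skeletal muscle, fat and mesothelial genes. Lung tissue holds most of these cell types, and a few genes (Lcn2, Mt1, Mt2, Cdkn1a) stand in 2 lists. Lists were tested with camera (preset correlation 0.01), which asks whether a list's genes rank higher or lower than the other genes, with adjustment over the 31 lists of a comparison. Camera with an estimated correlation and fry were run beside it. For each list, members were also counted after adjustment over the list alone.

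The naming rule took, for each comparison, the 6 largest rises and 6 largest falls among changed genes with at least 5 CPM in the higher group and, in comparisons of 2 groups, CPM ranges that did not overlap; up to 3 members of each list with the smallest p; and Il6, Cxcl1, Hmox1 and Cdkn2a. Symbols of predicted genes (Gm, LOC, Rik) were skipped. The genes named in the text are a selection of 239 values from that pool, made with the values in view. The closing section adds 21 differences between ages in the change from sham, for genes named in the comparisons with sham. A2m in old 1 day lungs and Mup7 were left out because a group was at 0 in every library.

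Alternatives named in advance were DESeq2 size factors, no low-count filter, a filter of at least 1 CPM in 4 libraries, a replicate block, only the groups compared, single transcripts, limma 3.58.1 (trend) on log2(TPM + 1) and on log2(TPM + 0.1), the DESeq2 1.42.0 Wald test, fry, camera with an estimated correlation, and leaving out each library of a comparison in turn. After a trend of counts with GC content was seen, 2 more were added: offsets that remove each library's smooth trend on GC content (natural spline, 5 df), and on GC content and transcript length together. GC content came from transcript sequences and was found for 18134 genes, 92.1% of those tested; the 13 mitochondrial mRNAs and the genes without a value were held out of the trend and got no offset, so their values are not corrected. Correlations with GC content were taken over the 14014 genes with a GC value and an average of at least 1 on the log2 CPM scale.

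Tests were tried on simulated data with the real depths and spreads. Of 50 genes changed 2-fold, 74% were recovered for young 1 h against young sham, 64% for old 1 day against old sham, and 44% for the difference between ages at 1 h, with 9, 9 and 8 false calls among 19690 genes. At 4-fold the shares were 90%, 92% and 84%. With a GC trend simulated in the young reperfused libraries, false calls for that difference rose to 335 and fell to 5 with it removed. That cannot test the removal of the real trend. A cell cycle list changed 1.5-fold was the 1 list called of 31, but correlated members were not simulated. Library totals, mitochondrial shares and named genes' counts were checked for outliers within a group of 4 (Dixon's ratio over its 95% critical value).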

Results

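Lung RNA was sequenced in 24 libraries, 4 in each of 6 groups: young sham, young 1 h, young 1 day, old sham, old 1 h and old 1 day, where 1 h and 1 day are the times of reperfusion after clamping of the left hilum. Library totals ran from 29523653 to 38426872 estimated reads in young sham, 27850677 to 42241406 in young 1 h and 28611963 to 44504824 in young 1 day. They ran from 29863241 to 43600154 in old sham, 29144117 to 32909231 in old 1 h and 30136663 to 33835569 in old 1 day. All 19690 genes that passed the low-count filter were tested in each comparison. Values without a unit are log2 changes with their SE, and CPM are means with the SD over 4 libraries. Where the count of a list's members is followed by 1 number in parentheses, that is the count adjusted over the list alone; a second number is the count over all genes with the GC trend described next removed. In each comparison of 2 groups, the 4 libraries of 1 group lay outside the range of the other for every gene named below, except where a gene is said to overlap.

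Mitochondrial mRNAs and AT-rich genes separated the young reperfused libraries from the others. The mitochondrial share of the counts was 2.93% ± 0.348 (SD, n = 4) in young sham, 1.36% ± 0.193 in young 1 h and 1.07% ± 0.296 in young 1 day, against 3.82% ± 0.408, 3.64% ± 0.517 and 2.86% ± 0.268 in old sham, old 1 h and old 1 day. Spearman's rho of a library's expression, relative to the mean of all libraries, with GC content over 14014 genes was 0.35 to 0.51 in young 1 h and 0.25 to 0.52 in young 1 day. It was -0.38 to -0.28 in young sham, -0.42 to -0.33 in old sham, -0.36 to -0.22 in old 1 h and -0.24 to -0.03 in old 1 day. These are correlations across genes, which are not independent replicates. Comparisons that involve a young reperfused group differ in this GC trend between the groups compared, and the lists called in them are given with and without the trend. The removal was chosen after seeing the data.

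**Figure D1:**
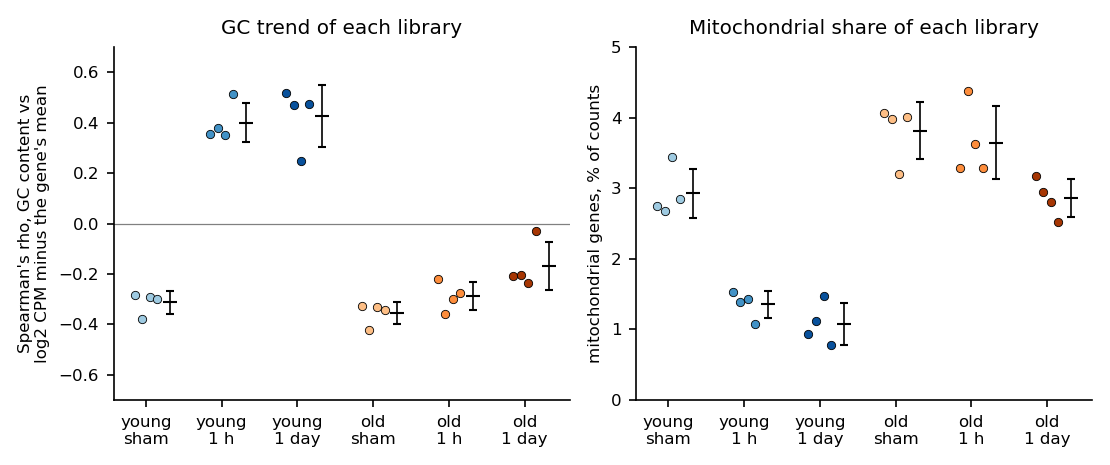
Spearman's rho of each library's relative expression with GC content across 14014 genes, and the mitochondrial share of its counts in percent, for the 6 groups (a point per library, 4 per group). The young 1 h and young 1 day libraries lie at rho 0.25 to 0.52 and the other 16 at or below -0.03.

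The first comparison asks what 1 h of reperfusion changed in young lungs. The inducible chaperones Hspa1b (Entrez 15511, chromosome 17, 34956429 to 34959238, mm10) and Hspa1a (Entrez 193740, chromosome 17, 34969359 to 34972156) rose most among the genes named, from 16.6 ± 1.55 to 2682 ± 797 CPM and from 17.0 ± 1.84 to 2598 ± 736 CPM (SD, n = 4). Their log2 changes were 7.34 ± 0.37 and 7.26 ± 0.36 (adjusted p = 1.98e-11 for each). These paralogs are nearly identical in sequence, so their split is uncertain. Arc (Entrez 11838, chromosome 15, 74669081 to 74672570), an activity-induced gene, rose from 1.79 ± 1.2 to 75.8 ± 25.7 CPM, and the stress transcription factor Atf3 rose 30.7-fold. The neutrophil-attracting chemokine Cxcl3 rose by 4.61 ± 0.93 from 0.346 ± 0.162 CPM. Among the largest falls were mitochondrial mRNAs. ND6 (Entrez 17722, chromosome M, 13552 to 14070) was 12.3-fold lower (-3.62 ± 0.42), ATP8 7.36-fold lower and ND3 5.01-fold lower, and the 13 mitochondrial mRNAs ranged from -3.62 to -0.20.

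Of the 14 heat shock genes 11 rose in young 1 h lungs (11 rose and 1 fell adjusted over the list alone, 13 rose with the GC trend removed), among them the co-chaperone Dnajb1 (2.95 ± 0.16). Immediate early genes rose in 22 of 26 cases (23 adjusted over the list alone, 22 with the trend removed). Ier5 was at 2.18 ± 0.23 and the growth regulator Myc at 2.36 ± 0.30. Inflammatory genes rose in 19 of 27 cases (20 and 17). The NF-kB regulator Bcl3 was at 2.43 ± 0.32 and the leukocyte adhesion molecule Icam1 at 0.99 ± 0.14. Of 18 endothelial activation and coagulation genes 15 rose and 1 fell (the same adjusted over the list alone, 14 and 0 with the trend removed): the adhesion molecule Sele rose by 4.23 ± 0.57 and the urokinase receptor Plaur by 2.24 ± 0.22. NRF2 targets and metallothioneins rose in 9 of 15 cases (10 and 9). Srxn1 was at 2.09 ± 0.19, Mt1 at 3.22 ± 0.44 and the heme-degrading Hmox1 at 1.72 ± 0.26. ER stress and integrated stress response genes rose in 10 of 16 (11 and 8). The transcription factor Atf4 was at 1.47 ± 0.12 and Ddit3 at 1.72 ± 0.16. Hypoxia-inducible genes rose in 9 of 18 (9 rose and 1 fell over the list alone and with the trend removed). The glucose transporter Slc2a1 was at 1.88 ± 0.23 and hexokinase Hk2 at 1.77 ± 0.18. Oxidative phosphorylation genes encoded in the nucleus rose in 15 of 21 and 1 fell (the same over the list alone, 14 and 0 with the trend removed). Cox4i1 was at 0.89 ± 0.09 and 0.51 with the trend removed. Neutrophil markers rose in 6 of 18 (6 and 8), with the decoy receptor Il1r2 at 2.60 ± 0.55. Monocyte and recruited macrophage markers rose in 6 of 18 (6 and 4), with Lgals3 at 1.25 ± 0.13. Of 13 glucocorticoid-induced genes 7 rose and 1 fell (7 and 2 over the list alone, 7 and 1 with the trend removed), with the cell cycle inhibitor Cdkn1a at 1.97 ± 0.31.

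Camera called these 11 lists, in the order given, with adjusted p = 3.1e-19, 1.97e-10, 2.23e-05, 2.58e-07, 1.8e-06, 1.69e-05, 0.00698, 2.56e-06, 0.0406, 0.0491 and 0.0491. With an estimated correlation the adjusted p = 0.021, 0.49, 0.652, 0.173, 0.173, 0.173, 0.652, 0.652, 0.962, 0.71 and 0.902, so the heat shock list alone stayed called. Endothelial markers rose in 10 of 21 cases and 2 fell (11 and 3 over the list alone), but 2 rose and 1 fell with the GC trend removed (adjusted p = 0.356). The vascular gene Tmem100 fell by 1.52 (SE 0.22). Senescence and secretory phenotype genes rose in 5 of 16 and 1 fell, by either adjustment (adjusted p = 0.0667). The epidermal growth factor family member Areg was at 3.52 ± 0.35. The mesothelial genes Wt1 (-2.69 ± 0.72) and Msln (-1.81 ± 0.53) fell, as did Lrrn4 (-2.14 ± 0.63) and the circadian factor Hlf (-1.81 ± 0.46; -2.56 without young 1 h 2), whose libraries overlap between groups. In the list of skeletal muscle, fat and mesothelial genes 3 of 9 fell and 1 rose by either adjustment, with a median of 0.92 and a mean of 0.44 but a test pointing down (adjusted p = 0.751). Il6 was at 61.5 ± 22.5 against 18.6 ± 5.24 CPM in young sham, a log2 change of 1.73 ± 0.77 (adjusted p = 0.0796), and 2.27 with adjusted p = 0.0287 when the GC trend was removed and 1.72 with adjusted p = 0.00221 when fitted with these groups alone. Cxcl1 rose by 1.80 ± 0.69 (adjusted p = 0.0424), a call that ended without young sham 1, 2, 3 or 4 (1.75, 1.86, 1.62 and 1.87) or without young 1 h 1 or 3 (1.67 and 1.48). It did not pass with no low-count filter or in limma either. In all, 4180 genes were higher and 3958 lower, 1039 and 992 of them by more than 2-fold.

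In old lungs the same question was asked at 1 h. Hspa1b rose from 16.1 ± 3.02 to 1420 ± 406 CPM (SD, n = 4), by 6.46 ± 0.35 (adjusted p = 1.36e-10, split with Hspa1a uncertain), and Arc from 1.87 ± 0.814 to 74.9 ± 7.35 CPM (5.31 ± 0.38). The serine protease Prss22 (Entrez 70835, chromosome 17, 23993534 to 24000722) rose by 5.39 ± 0.74, from 0.136 ± 0.13 CPM. The transcription factor Fosl1 rose by 4.97 ± 0.67 and the pattern recognition protein Ptx3 by 4.93 ± 1.38 (6.53 without old sham 4). Falls were led by the sulfotransferase Chst4 (-4.40 ± 0.65) and the mesothelial genes Lrrn4 (-3.28 ± 0.66) and Upk3b (-3.24 ± 0.67), which were at -3.58, -2.45 and -2.51 without old sham 1. No GC trend was seen here (rho -0.018), and the 13 mitochondrial mRNAs were at -0.06 to 0.13.

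Heat shock genes rose in 13 of 14 cases in old 1 h lungs (14 adjusted over the list alone). Dnajb1 was at 2.76 ± 0.16. Immediate early genes rose in 21 of 26 (24 adjusted over the list alone), inflammatory genes in 13 of 27 (18) and endothelial activation and coagulation genes in 13 of 18 (14). Examples were the granulocyte growth factor Csf3 (4.41 ± 0.80), the cytokine signal inhibitor Socs3 (2.82 ± 0.49), Sele (4.08 ± 0.54) and Plaur (1.85 ± 0.21). Neutrophil markers rose in 17 of 18 (18), with the chemokine receptor Cxcr2 (Entrez 12765, chromosome 1, 74153994 to 74161246) at 1.67 ± 0.37 and the histamine-forming Hdc at 1.47 ± 0.27. Monocyte and recruited macrophage markers rose in 8 of 18 (8), with Adam8 at 1.88 ± 0.29 and the endotoxin co-receptor Cd14 at 2.16 ± 0.39. T and NK cell markers rose in 8 of 20 (9). The costimulator Icos was at 1.11 ± 0.23 and granzyme Gzmb at 1.76 ± 0.39. NRF2 targets rose in 10 of 15 (11). Srxn1 was at 1.49 ± 0.19 and Hmox1 at 1.32 ± 0.26. ER stress genes rose in 11 of 16 (11 rose and 1 fell), hypoxia-inducible genes rose in 9 of 18 and 2 fell (11 and 3), with the vasodilator peptide Adm at 2.11 ± 0.38, and p53 targets and senescence genes each rose in 5 of 16 with 1 fall, by either adjustment, with Areg at 3.29 ± 0.35. Without old sham 1 the inflammatory genes that rose numbered 8, without old 1 h 1 the neutrophil markers numbered 9, and the T and NK cell markers numbered 5 without old sham 1, old sham 2, old 1 h 1 or old 1 h 3 and 3 without old sham 3.

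Alveolar type 1 markers fell in all 14 cases in old 1 h lungs (14 over the list alone), among them the tight junction gene Cldn18 (Entrez 56492, chromosome 9, 99690796 to 99717267; -0.79 ± 0.12) and the proteoglycan Spock2 (-0.95 ± 0.16). Alveolar type 2 markers fell in 5 of 16 (5). Surfactant protein Sftpc was at -0.71 ± 0.18 and the phosphate transporter Slc34a2 at -1.42 ± 0.30. Endothelial markers fell in 4 of 21 (4). Camera called the 14 lists of heat shock, immediate early, inflammatory, endothelial activation, neutrophil, monocyte, T and NK cell, NRF2, ER stress, hypoxia, p53, senescence, type 1 and type 2 genes with adjusted p = 1.11e-32, 5.07e-17, 1.39e-08, 1.3e-10, 1.84e-07, 0.000404, 0.000495, 8.68e-09, 6.46e-07, 0.00181, 0.012, 0.0491, 3.73e-10 and 0.00192. With an estimated correlation the adjusted p = 0.00135, 0.132, 0.269, 0.0611, 0.269, 0.245, 0.292, 0.0709, 0.0611, 0.358, 0.245, 0.358, 0.132 and 0.513 in that order. Endothelial markers, glucocorticoid-induced genes (6 rose and 1 fell of 13, 7 and 1 over the list alone), oxidative phosphorylation genes (4 rose of 21 by either adjustment, 2 without old 1 h 2) and the 10 cardiac muscle genes (median 1.36) were called with adjusted p = 0.0117, 0.0013, 0.0238 and 0.0266, and adjusted p = 0.358, 0.366, 0.706 and 0.704 with an estimated correlation. Il6 was at 113.5 ± 21.5 against 27.5 ± 20.4 CPM (2.05 ± 0.77, adjusted p = 0.059), and without old sham 2 the change was 2.61 with adjusted p = 0.0396. Cxcl1 was at 83.2 ± 13.7 against 29.0 ± 18.2 CPM (1.52 ± 0.68, adjusted p = 0.109). Fitted with these groups alone, both genes passed, and Il6 passed in DESeq2 and in limma on log2(TPM + 1) too. In all, 2475 genes were higher and 2487 lower, 861 and 363 of them by more than 2-fold.

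Changes at 1 h can be compared between ages because they share no libraries. Across the 19690 genes, Pearson's r of the log2 changes was 0.48 and Spearman's rho 0.52, over genes that are not independent replicates. Among called genes 1497 rose in both ages where 525.4 would by independence, 1326 fell in both (499.9), and 183 moved in opposite directions. With the GC trend removed these were 1340 (334.8), 1951 (654.2) and 86.

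**Figure D2:**
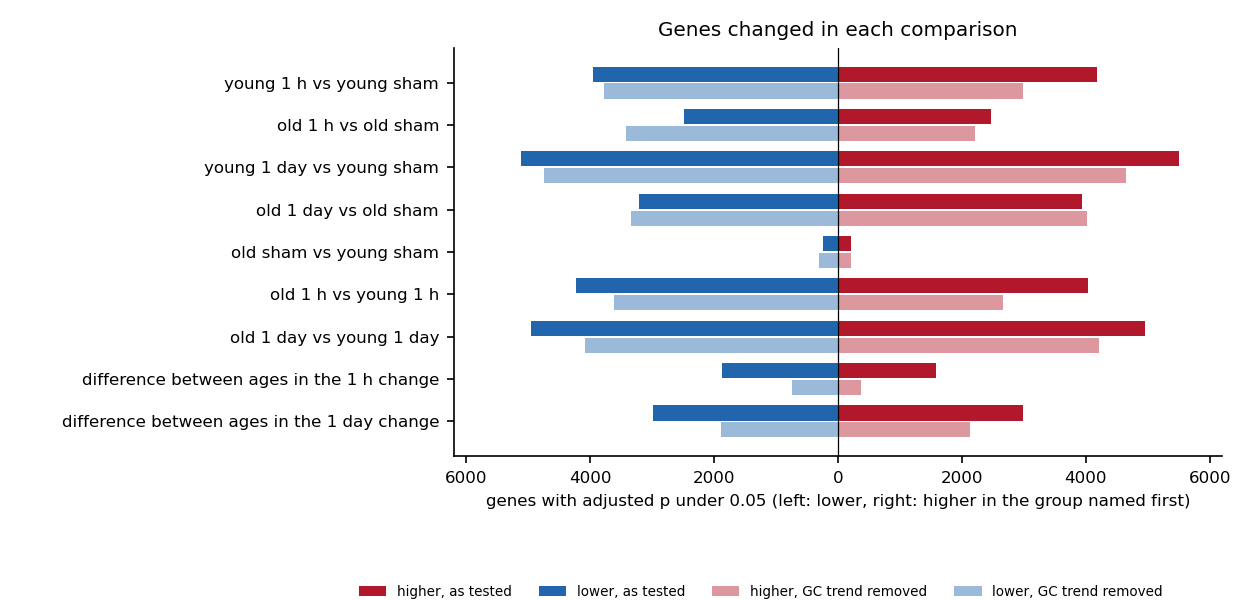
Number of genes with adjusted p under 0.05 in each of the 9 comparisons, higher and lower shown apart, with all libraries and with the GC trend of the libraries removed. The counts run from 454 for old against young sham to 10616 for young 1 day against young sham.

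At 1 day, young lungs were again compared with young sham. The macrophage arginase Arg1 (Entrez 11846, chromosome 10, 24915207 to 24927470) rose from 2.38 ± 0.382 to 298.4 ± 213 CPM (SD, n = 4), by 6.97 ± 0.58 (adjusted p = 5.76e-09), and the acute-phase gene Saa3 (Entrez 20210, chromosome 7, 46711998 to 46719615) from 2.67 ± 1.69 to 193.3 ± 107 CPM. Also among the largest rises were the macrophage-derived Cd5l (6.13 ± 0.94), the squamous epithelial gene Sprr1a (5.44 ± 0.58), the eosinophil-attracting chemokine Ccl24 (5.38 ± 0.84) and Cxcl3 (5.13 ± 0.93). The mitochondrial ND6 was 17.9-fold lower, the mesothelial Upk3b 11.1-fold lower and the immediate early gene Fosb 10.9-fold lower (-3.45 ± 1.12). Without young 1 day 3, ND6 was at -5.08, without young 1 day 2, Upk3b at -4.29 and Fosb at -4.31, and without young 1 day 4, Ccl24 at 4.72. The GC trend of this comparison had rho 0.4846.

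All 24 cell cycle genes rose in young 1 day lungs (24 adjusted over the list alone, 24 with the GC trend removed), with the replication licensing genes Mcm5 (Entrez 17218, chromosome 8, 75109468 to 75128439) at 2.70 ± 0.29 and Mcm2 (Entrez 17216, chromosome 6, 88883474 to 88898780) at 2.00 ± 0.22. Monocyte and recruited macrophage markers rose in 16 of 18 (16 and 14). Cd68 was at 2.24 ± 0.15 and Lgals3 at 2.16 ± 0.13. Without young 1 day 4 these markers numbered 10. Oxidative phosphorylation genes rose in 18 of 21 (18 rose and 1 fell over the list alone, 18 with the trend removed), heat shock genes rose in 10 of 14 and 1 fell (the same by each count), and ER stress genes rose in 10 of 16 and 2 fell (10 and 2 over the list alone, 9 and 3 with the trend removed). The ER co-chaperone Sdf2l1 was at 3.04 ± 0.23. Acute-phase and complement genes rose in 11 of 18 and 1 fell (12 and 1, 9 and 1). T and NK cell markers fell in 14 of 20 (15 and 14). The cytokine receptor Il7r was at -2.36 ± 0.22 and the costimulatory receptor Cd28 (Entrez 12487, chromosome 1, 60746388 to 60773359) at -2.38 ± 0.25. With the trend removed these were -1.80 and -1.90. Ciliated cell markers fell in 14 of 16 (14 and 15). The dynein gene Dnah12 was at -1.98 ± 0.22. Camera called these 8 lists, in that order, with adjusted p = 3.19e-07, 7.79e-08, 4.42e-08, 0.0159, 0.0159, 0.0186, 0.000494 and 0.000477, and adjusted p = 0.772, 0.242, 0.694, 0.772, 0.694, 0.694, 0.694 and 0.79 with an estimated correlation. None of them stayed called.

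Other lists in young 1 day lungs were not called. Interferon-stimulated genes rose in 11 of 20 and 1 fell (the same over the list alone, adjusted p = 0.0746). Isg15 was at 2.11 ± 0.32 and the nucleic acid sensor Zbp1 at 2.13 ± 0.30. Senescence and secretory phenotype genes rose in 9 of 16 and 1 fell (9 and 2, adjusted p = 0.136). The protease inhibitor Timp1 was at 3.98 ± 0.37. Of 16 alveolar type 2 markers 7 rose and 1 fell (7 and 0, adjusted p = 0.213; 5 and 1 with the trend removed). Sftpb was at 1.26 ± 0.19 and the fatty acid synthase Fasn at 1.19 ± 0.21. Extracellular matrix and fibroblast genes rose in 7 of 18 and 1 fell (the same over the list alone, adjusted p = 0.377). Tenascin Tnc was at 3.34 ± 0.49. Glucocorticoid-induced genes rose in 3 of 13 and 6 fell (3 and 7, adjusted p = 0.3), with the transcription factor Klf9 at -1.60 ± 0.19, and p53 targets rose in 3 of 16 and 7 fell by either adjustment (adjusted p = 0.377), with Trp53inp1 at -2.64 ± 0.23. Further single genes were the macrophage receptor Marco (3.54 ± 0.63), the lipid carrier Fabp1 (-1.98 ± 0.35), lactate dehydrogenase Ldha (1.56 ± 0.13), the nuclear receptor Nr4a3 (-3.38 ± 0.48) and Hmox1 (2.43 ± 0.27). Il6 fell from 18.6 ± 5.24 to 2.71 ± 1.5 CPM (-2.81 ± 0.85, adjusted p = 0.00897), and Cxcl1 was at 5.84 ± 1.95 CPM (-1.47 ± 0.71, adjusted p = 0.0871), a change that passed when fitted with these groups alone and in DESeq2 and limma. The senescence marker Cdkn2a rose from 0.46 ± 0.219 to 1.14 ± 0.228 CPM (1.30 ± 0.50, adjusted p = 0.0338). It did not pass without young sham 1, 2 or 3 (1.22, 1.29 and 1.06), without young 1 day 1 or 4 (1.16 and 1.32), with the GC trend removed (0.86, adjusted p = 0.169), with no low-count filter or in limma. In all, 5497 genes were higher and 5119 lower, 1592 and 1870 of them by more than 2-fold. With the GC trend removed 9385 genes were called, 7586 of them shared.

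Old lungs at 1 day were compared with old sham. Saa3 rose from 1.80 ± 0.716 to 332.1 ± 191 CPM (SD, n = 4), by 7.54 ± 0.91 (adjusted p = 3.84e-06), and Arg1 from 1.41 ± 0.294 to 218.4 ± 129 CPM, by 7.26 ± 0.59. Saa1, whose reads may be shared with Saa2, was at 6.32 ± 3.62 CPM in old 1 day lungs and at 0 in all old sham libraries but old sham 2 (0.165 CPM), so its log2 change of 7.16 ± 0.88 rests on a base near 0 (10.71 without old sham 2, a fitted value against a group at 0). The neutrophil chemokine Cxcl5 rose by 6.63 ± 0.95 (5.24 without old 1 day 3) and the granule protein Ngp by 6.33 ± 1.60 (3.42 without old 1 day 2). Among the largest falls were the membrane protein gene Gsg1l (Entrez 269994, chromosome 7, 125878412 to 126082757; 24.9-fold lower, -5.72 on the log2 scale without old 1 day 1), the collagen tail gene Colq (12.3-fold lower) and the ligand Wnt10b (10.5-fold lower).

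Monocyte and recruited macrophage markers rose in 14 of 18 cases in old 1 day lungs (15 adjusted over the list alone). Cd63 was at 1.61 ± 0.11. Acute-phase and complement genes rose in 12 of 18 (12), with lipocalin Lcn2 from 119.5 ± 44.2 to 2257 ± 1480 CPM (4.24 ± 0.50), and NRF2 targets rose in 11 of 15 (11), with metallothionein Mt2 at 3.22 ± 0.46 and Hmox1 at 2.22 ± 0.27. Endothelial activation and coagulation genes rose in 11 of 18 and 1 fell by either adjustment. The protease Adamts4, whose libraries overlap, was at 3.66 ± 0.63 (3.00 without old 1 day 2) and tissue factor F3 at 2.08 ± 0.31. ER stress genes rose in 11 of 16 and 1 fell (12 and 1), glucocorticoid-induced genes rose in 7 of 13 (7 and 1), and senescence and secretory phenotype genes rose in 7 of 16 and 1 fell by either adjustment. Timp1 was at 5.10 ± 0.40. Inflammatory genes rose in 14 of 27 (16), with Csf3 at 4.75 ± 0.81 (3.83 without old 1 day 3), and neutrophil markers in 14 of 18 (14), with lactoferrin Ltf at 4.83 ± 1.22 (5.44 without old sham 4) and Wfdc21 at 2.79 ± 0.57 (2.12 without old 1 day 2). Inflammatory genes that rose numbered 9 without old sham 1, old 1 day 2 or old 1 day 3 and 8 without old sham 4. Neutrophil markers that rose numbered 8 without old sham 1, 7 without old sham 3 or old sham 4 and 6 without old 1 day 2. Of 24 cell cycle genes 5 rose (2 over the list alone, and 2 without old sham 1, 2 or 4 or old 1 day 1; adjusted p = 0.285). Mcm5, whose libraries overlap, was at 1.04 ± 0.28 and at 0.56 without old 1 day 1. It did not pass when fitted with these groups alone (1.02, adjusted p = 0.0503). Platelet factor Pf4 rose by 2.31 ± 0.30, 1 of 11 red cell and platelet genes to do so by either adjustment (adjusted p = 0.263).

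Lymphocyte and antigen presentation genes fell in old 1 day lungs: all 13 B cell markers (13 over the list alone), 16 of 20 T and NK cell markers (16) and 9 of 10 MHC class II genes (10). Examples were the IgM receptor Fcmr (-2.20 ± 0.38), the transcription factor Spib (-1.48 ± 0.25), the T cell co-receptor Cd8b1 (-1.45 ± 0.18), H2-Ob (-2.17 ± 0.30) and H2-Eb1 (-0.94 ± 0.16). Ciliated cell markers fell in 15 of 16 (16), with the microtubule gene Tppp3 at -1.24 ± 0.11, and type 1 markers fell in 10 of 14 and 1 rose by either adjustment, with Rtkn2 at -1.60 ± 0.30. Sftpc, a type 2 product, fell by 1.15 (SE 0.18), and Cyp2f2, a club cell enzyme, fell by 2.29 (SE 0.33), 1 of 4 falls among 12 club and secretory airway markers by either adjustment (adjusted p = 0.0758). Camera called monocyte, acute-phase, NRF2, endothelial activation, ER stress, glucocorticoid, senescence, inflammatory, neutrophil, B cell, T and NK cell, MHC class II, ciliated and type 1 lists with adjusted p = 6.21e-12, 1.43e-06, 6.51e-06, 0.00192, 0.000389, 0.00405, 0.0106, 0.00253, 0.00425, 3.16e-08, 5.8e-08, 1.32e-06, 1.07e-10 and 0.00234, and adjusted p = 0.0341, 0.151, 0.206, 0.428, 0.203, 0.505, 0.253, 0.556, 0.556, 0.255, 0.168, 0.253, 0.246 and 0.505 with an estimated correlation, in that order. Heat shock (6 rose of 14, 7 and 1 over the list alone, 3 without old sham 4), hypoxia-inducible (7 rose and 1 fell of 18, 9 and 2, 11 rose without old 1 day 1), oxidative phosphorylation (5 rose of 21 by either adjustment) and cardiac muscle genes (3 fell of 10, 5 over the list alone and also without old 1 day 1) were called with adjusted p = 0.0106, 0.0251, 0.0437 and 0.0206, and adjusted p = 0.505, 0.556, 0.657 and 0.634 with an estimated correlation. The cardiac actin Actc1 was at -3.21 ± 0.73, and at -4.51 without old 1 day 1 and -2.36 without old sham 4. Il6 was at 40.3 ± 41.1 against 27.5 ± 20.4 CPM (0.55 ± 0.75, adjusted p = 0.602), and at -0.34 in limma on log2(TPM + 1) and -0.034 without old 1 day 3. Cxcl1 was at 74.7 ± 96.9 against 29.0 ± 18.2 CPM (1.36 ± 0.68, adjusted p = 0.123), passed without old 1 day 1 (1.74, adjusted p = 0.0333) and was at -0.13 without old 1 day 3. The libraries of both genes overlap. In all, 3945 genes were higher and 3211 lower, 984 and 1331 of them by more than 2-fold.

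Across ages, the log2 changes at 1 day had Pearson's r 0.35 and Spearman's rho 0.52 over all genes. Among called genes 2589 rose in both ages (1101.4 by independence), 1751 fell in both (834.8) and 322 moved in opposite directions.

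**Figure D3:**
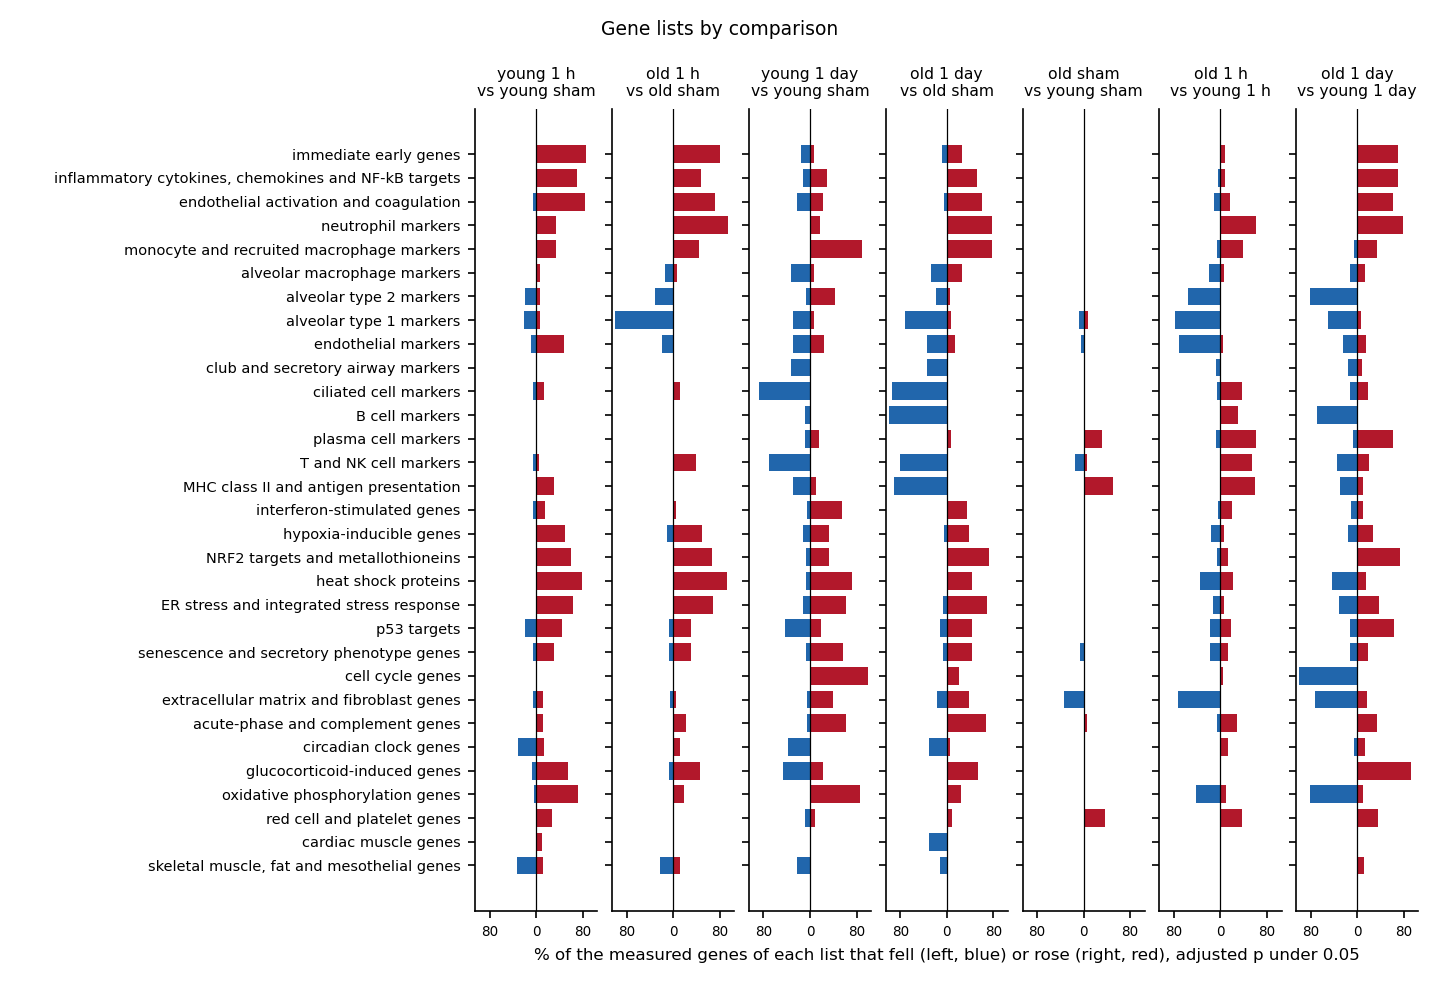
Percent of the measured genes of each of the 31 gene lists (rows) that fell (left bars) or rose (right bars) with adjusted p under 0.05. Each column is a comparison of 2 groups. The median log2 change of cell cycle genes, which is not drawn, was 1.92 in young 1 day against young sham, 0.27 in old 1 day against old sham and -1.70 in old against young 1 day lungs.

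Old and young sham lungs were compared to give the difference by age without clamping. Immunoglobulin genes were higher in old: Ighg2c (Entrez 404711, chromosome 12, 113287389 to 113288932) was at 65.9 ± 69.5 against 0.327 ± 0.0525 CPM (SD, n = 4; 7.63 ± 1.64, adjusted p = 0.0158), Ighg2b at 6.48 ± 1.38, Igha at 3.18 ± 0.66 and the joining chain Jchain (Entrez 16069, chromosome 5, 88519809 to 88527897) at 4.47 ± 0.80. Reads of immunoglobulin constant genes may be shared between them. Plasma cell markers were higher in 4 of 13 cases (8 adjusted over the list alone) and MHC class II genes in 5 of 10 (7). H2-Eb1 was at 0.77 ± 0.16 and the invariant chain Cd74 at 0.65 ± 0.14. Extracellular matrix and fibroblast genes were lower in 6 of 18 (11), with the collagens Col3a1 (Entrez 12825, chromosome 1, 45311538 to 45349706; 952.3 ± 138 in young and 239.4 ± 41.5 CPM in old, -1.99 ± 0.40), Col5a2 (-1.29 ± 0.22) and Col6a1 (-1.03 ± 0.19). Red cell and platelet genes were higher in 4 of 11 (5), with the platelet genes Itga2b at 1.23 ± 0.15 and Gp9 at 1.37 ± 0.23. The list's median was -0.08 and its mean 0.34, with a test pointing up. Camera called these 4 lists with adjusted p = 6.91e-08, 3.62e-09, 2.19e-13 and 8.57e-06, and adjusted p = 0.297, 0.297, 0.0321 and 0.353 with an estimated correlation, which kept the matrix list alone. Albumin (Alb, Entrez 11657, chromosome 5, 90460870 to 90476602) was 26.2-fold lower in old sham, Veph1 15.5-fold, the endopeptidase Phex 5.58-fold and the acyltransferase Mboat2 4.62-fold lower.

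Further differences between sham groups were in Igfbp2 (1.04 ± 0.20), Igfbp7 (-0.68 ± 0.12), the complement gene C4b (0.85 ± 0.21), the basement membrane collagen Col4a3 (-0.66 ± 0.18), the apelin receptor Aplnr (-1.32 ± 0.27), the NK cell receptors Klrb1c (-1.15 ± 0.19) and Ncr1 (-1.55 ± 0.35), and granzyme Gzmk (3.97 ± 0.91). T and NK cell markers were higher in 1 of 20 and lower in 3 (1 and 4 over the list alone, adjusted p = 0.502), with a median and mean of 0.05 and 0.02 and a test pointing down. Cdkn2a was at 0.935 ± 0.581 against 0.46 ± 0.219 CPM (1.02 ± 0.50, adjusted p = 0.376), Il6 at 0.56 ± 0.76 (adjusted p = 0.827; -0.013 without old sham 2) and Cxcl1 at 0.85 ± 0.68 (adjusted p = 0.652), all with overlapping libraries. Another 9 lists were called by camera: immediate early, inflammatory, neutrophil, monocyte, ciliated and NRF2 genes up (medians 0.52, 0.56, 0.57, 0.37, 0.36 and 0.15), with adjusted p = 0.000741, 0.0201, 0.0201, 0.000614, 0.00691 and 0.0355, and type 2, type 1 and endothelial markers down (medians -0.26, -0.14 and -0.15), with adjusted p = 0.004, 0.0436 and 0.00506. With an estimated correlation the adjusted p = 0.831, 0.831, 0.831, 0.353, 0.831, 0.831, 0.831, 0.831 and 0.572 in that order. In all, 214 genes were higher and 240 lower in old sham, 146 and 76 of them by more than 2-fold.

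Calls and values between sham groups depended on single libraries. Without old sham 3, Ighg2c was at 6.95 and Ighg2b at 5.77, and without old sham 2, albumin at -5.32. Plasma cell markers that were higher numbered 1 without young sham 1 and 2 without young sham 2 or 4. MHC class II genes that were higher numbered 0 without young sham 1, 1 without young sham 2 or 4, 2 without old sham 1 or 3, and 3 without old sham 2 or 4. Ighg2c did not pass without young sham 1, 2 or 4 (7.62, 7.69 and 7.66), nor Ighg2b without the same libraries (6.63, 6.82 and 6.24). H2-Eb1 (0.73) and Igha (3.16) did not pass without young sham 1, Aplnr without old sham 3 (-1.22), and Ncr1 without young sham 1 or 2 (-1.5 and -1.38) or old sham 2 or 3 (-1.49 and -1.47). Gzmk did not pass without young sham 1, 3 or 4 (4.40, 3.59 and 3.60) or old sham 1 (3.31), and Cd74 without young sham 1, 2 or 4 (0.64, 0.62 and 0.62) or old sham 3 (0.61). C4b did not pass without young sham 1, 2, 3 or 4 (0.91, 0.93, 0.76 and 0.78) or old sham 1 or 3 (0.63 and 0.77), and Col4a3 without any sham library but old sham 2 (-0.73 to -0.57). The count of 454 genes was 225, 233, 261, 271 and 259 without young sham 1, young sham 2, young sham 4, old sham 1 and old sham 3, and C4b did not pass when fitted with the sham groups alone or in limma, nor Col4a3 with no low-count filter.

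Reperfused lungs at 1 h were compared between ages. Ighg2c was at 474.0 ± 687 CPM in old and 0.534 ± 0.517 CPM in young (SD, n = 4; 9.87 ± 1.71, adjusted p = 0.000148), and Jchain was higher by 5.17 ± 0.83. Old 1 h 1 was at 1499 CPM of Ighg2c and the other old 1 h libraries at 33.86 to 219.4. Without it the differences were 8.03 and 4.56, and Ighg2c was at 10.68 without young 1 h 2. Neutrophil markers were higher in old in 11 of 18 cases (14 adjusted over the list alone, 8 with the GC trend removed), with the growth factor receptor Csf3r (Entrez 12986, chromosome 4, 126023441 to 126044975) at 1.54 ± 0.30, Cxcr2 at 1.58 ± 0.37 and the lectin Clec4e at 2.22 ± 0.58. These markers numbered 5 without young 1 h 1 or young 1 h 2 and 3 without old 1 h 1. T and NK cell markers were higher in 11 of 20 (11 and 9), with Cd28 at 1.76 ± 0.24, and monocyte and recruited macrophage markers were higher in 7 of 18 and lower in 1 (9 and 1, 4 and 0), with the chemokine receptor Ccr2 at 1.83 ± 0.35 and 1.24 with the trend removed. Plasma cell markers were higher in 8 of 13 and lower in 1 (10 and 1, 8 and 0), and MHC class II genes were higher in 6 of 10 (7 and 7; 3 without young 1 h 2 or old 1 h 2). Type 1 markers were lower in 11 of 14 (11 and 12), with Cldn18 at -0.97 ± 0.12 and Emp2 at -0.98 ± 0.12, and endothelial markers were lower in 15 of 21 and higher in 1 (16 and 1, 15 and 0), with the receptor Tie1 at -1.0 ± 0.12 and the cadherin Cdh5 at -0.93 ± 0.13. Type 2 markers were lower in 9 of 16 (10 and 8), with Sftpb at -1.19 ± 0.19, and extracellular matrix genes in 13 of 18 (14 lower and 1 higher over the list alone, 11 lower with the trend removed), with Col3a1 at -2.31 ± 0.41 and Col6a1 at -1.5 ± 0.19.

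Oxidative phosphorylation genes were lower in old 1 h lungs in 9 of 21 cases and higher in 2 (9 and 2 over the list alone, 13 and 0 with the trend removed). Ndufa2 was at -1.11 ± 0.13 and Cox4i1 at -0.65 ± 0.09. Ciliated cell markers were higher in 6 of 16 and lower in 1 by either adjustment (5 and 0 with the trend removed). Itga2b was higher by 0.72 ± 0.15 and Sprr1a lower (-2.46 ± 0.49). Camera called the neutrophil, T and NK cell, monocyte, plasma cell, MHC class II, type 1, endothelial, type 2, matrix, oxidative phosphorylation and ciliated lists with adjusted p = 0.00689, 0.00689, 0.047, 0.0156, 0.0345, 7.71e-06, 7.71e-06, 0.0034, 0.000106, 0.00689 and 0.0452, and adjusted p = 0.982, 0.982, 0.982, 0.982, 0.982, 0.79, 0.488, 0.982, 0.543, 0.982 and 0.982 with an estimated correlation. None of them stayed called. Il6 was at 113.5 ± 21.5 in old and 61.5 ± 22.5 CPM in young (0.88 ± 0.75, adjusted p = 0.369; 0.87 with adjusted p = 0.0246 when fitted with these groups alone), and Cxcl1 at 0.57 ± 0.66 (adjusted p = 0.523). The libraries of both overlap. In all, 4034 genes were higher and 4231 lower in old, 1304 and 401 of them by more than 2-fold. With the GC trend removed 6277 genes were called, 4844 of them shared.

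Reperfused lungs at 1 day were compared between ages in the same way. All 24 cell cycle genes were lower in old (24 adjusted over the list alone, 24 with the GC trend removed), with the mitotic kinase Plk1 (Entrez 18817, chromosome 7, 122159435 to 122169884) at 2.72 ± 1.16 in old against 14.6 ± 5.53 CPM in young (SD, n = 4; -2.43 ± 0.33, adjusted p = 3.85e-06), Mcm2 at -1.56 ± 0.22 and Mcm5 at -1.91 ± 0.28. Neutrophil markers were higher in 14 of 18 (15 and 13; 9 without old 1 day 2). Cxcr2 was at 2.30 ± 0.38 and the collagenase Mmp8 at 3.63 ± 0.65. Inflammatory genes were higher in 19 of 27 (19 and 17): Cxcl1 was at 74.7 ± 96.9 against 5.84 ± 1.95 CPM (3.68 ± 0.75; 2.20 without old 1 day 3), Il6 (Entrez 16193, chromosome 5, 30013114 to 30019975) at 40.3 ± 41.1 against 2.71 ± 1.5 CPM (3.93 ± 0.88), Csf3 at 3.38 ± 0.74 (2.47 without old 1 day 3) and Socs3 at 2.26 ± 0.48 (1.52 without old 1 day 2). The libraries of Il6, Csf3 and Socs3 overlap. Immediate early genes were higher in 18 of 26 (19 and 20; 8 without old 1 day 2). Klf6 was at 1.36 ± 0.15 and the mRNA decay factor Zfp36 at 2.12 ± 0.45 and 1.24 without old 1 day 2. Glucocorticoid-induced genes were higher in 12 of 13 (13 and 11), with the kinases Sgk1 (Entrez 20393, chromosome 10, 21882184 to 21999903) at 1.63 ± 0.24 and Map3k6 at 1.77 ± 0.37, whose libraries overlap. Endothelial activation genes were higher in 11 of 18 (13 and 10), NRF2 targets in 11 of 15 (12 over the list alone, 11 higher and 1 lower with the trend removed), with glutathione reductase Gsr at 1.23 ± 0.19, and p53 targets were higher in 10 of 16 and lower in 2 (10 and 2, 12 and 1), with the death regulator Pmaip1 at 1.87 ± 0.25.

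Type 2 markers were lower in old 1 day lungs in 13 of 16 cases (13 over the list alone, 14 with the trend removed), with Sftpc (Entrez 20389, chromosome 14, 70520941 to 70524081) at 4191 ± 738 against 9661 ± 1810 CPM (-1.21 ± 0.18) and Fasn at -1.45 ± 0.21. B cell markers were lower in 9 of 13 (9 and 5). Fcmr was at -1.87 ± 0.38 and Cd79b at -1.65 ± 0.34. Matrix genes were lower in 13 of 18 and higher in 3 (13 and 3, 12 and 1), with fibulin Fbln1 at -1.66 ± 0.22 and the fibroblast enzyme Inmt at -1.43 ± 0.23, and oxidative phosphorylation genes were lower in 17 of 21 and higher in 2 (18 and 2, 16 and 0), with Cox4i1 at -0.89 ± 0.09 and Ndufa2 at -1.25 ± 0.13. Red cell and platelet genes were higher in 4 of 11 (4 and 3). Camera called the cell cycle, neutrophil, inflammatory, immediate early, glucocorticoid, endothelial activation, NRF2, p53, type 2, B cell, matrix, oxidative phosphorylation and red cell lists with adjusted p = 1.35e-07, 0.00228, 0.00336, 0.00241, 0.0013, 0.00302, 0.00302, 0.0121, 8.15e-05, 0.00348, 0.00227, 4.57e-06 and 0.0331, and adjusted p = 0.62, 0.856, 0.856, 0.859, 0.62, 0.62, 0.62, 0.62, 0.62, 0.856, 0.62, 0.62 and 0.856 with an estimated correlation. None of them stayed called. Single genes with large differences were Ighg2c (7.64 ± 1.77; 6.42 without old 1 day 1 and 8.30 without young 1 day 2), the neutrophil gene Olfm4 (5.76 ± 0.89; 4.41 without old 1 day 2), Lcn2 (1.95 ± 0.45), the plasminogen-binding Clec3b (-2.77 ± 0.36) and Prdm8 (-2.66 ± 0.31). In all, 4948 genes were higher and 4944 lower in old, 1666 and 1129 of them by more than 2-fold. The change had rho -0.4974 with GC content, and 8292 genes were called with the trend removed, 6681 of them shared.

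**Figure D4:**
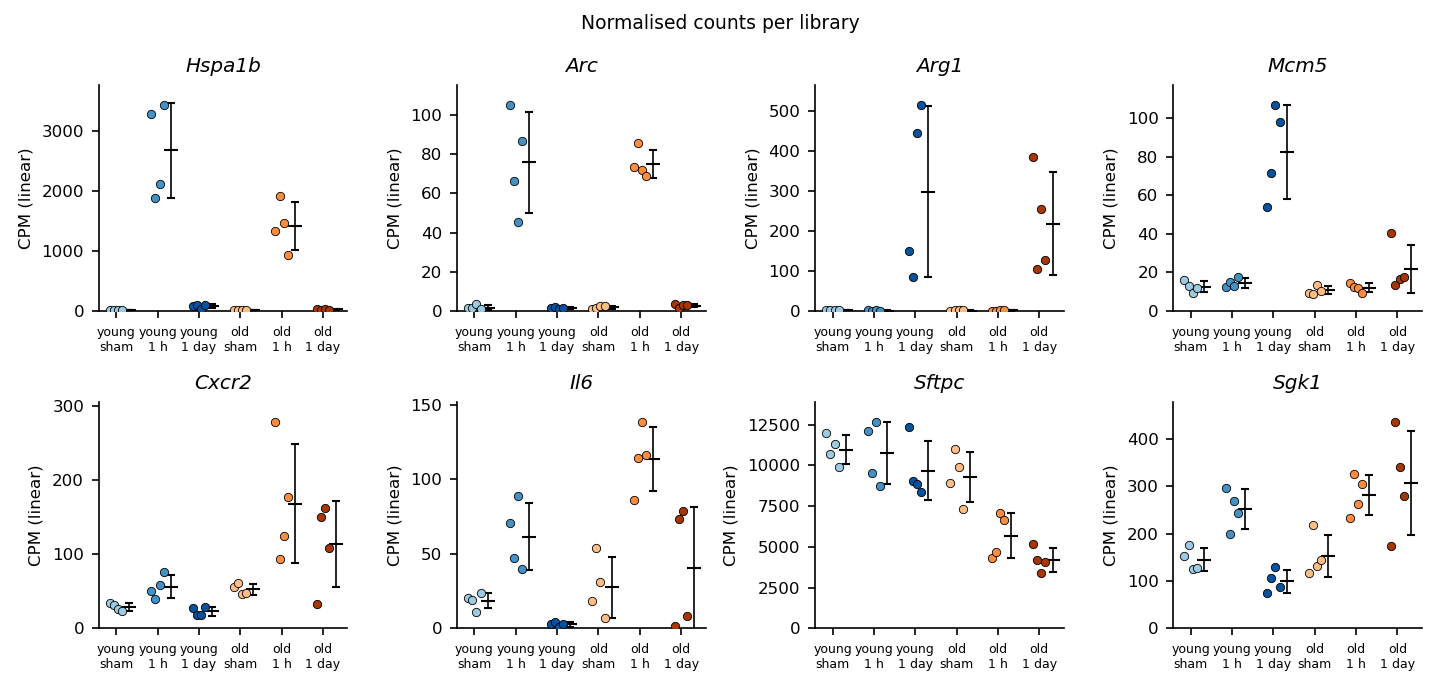
CPM of Hspa1b, Arc, Arg1, Mcm5, Cxcr2, Il6, Sftpc and Sgk1 on a linear axis in the 6 groups (a point per library, with mean and SD over 4 libraries). Mean Mcm5 is 12.7 CPM in young sham and 82.5 in young 1 day, and 10.7 in old sham and 22.0 in old 1 day.

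Whether the change from sham at 1 h differed between ages was tested as an interaction, in which positive values mean a higher change in old. The mitochondrial ND6 differed by 3.57 ± 0.55 (adjusted p = 0.000529, n = 4 per group) and the matrilin Matn4 by -1.42 ± 0.19. Oxidative phosphorylation genes were lower in 9 of 21 cases (9 lower and 1 higher adjusted over the list alone, 8 lower with the GC trend removed). Ndufa2 was at -1.07 ± 0.18 and Cox4i1 at -0.72 ± 0.13 and -0.39 with the trend removed. Type 1 markers were lower in 7 of 14 (8 over the list alone), but in 2 with the trend removed. Cldn18 was at -0.67 ± 0.17 and Aqp5 at -0.90 ± 0.20 and -0.49 (adjusted p = 0.147) with the trend removed. Endothelial markers were lower in 9 of 21 (11 over the list alone), in 1 with the trend removed, in 5 without young sham 2 or old sham 2 and in 4 without old sham 1. Tie1 was at -0.85 ± 0.16 and Cldn5 at -0.90 ± 0.20, and -0.54 (adjusted p = 0.0501) and -0.53 (adjusted p = 0.121) with the trend removed. T and NK cell markers were higher in 4 of 20 (9 over the list alone, 2 with the trend removed, and 2 without young sham 1, young sham 2, young 1 h 2 or old sham 3). Cd28 was at 1.72 ± 0.33. Il7r was at 0.93 ± 0.29 (adjusted p = 0.0327), and it did not pass without young sham 1 or 2 (0.91 and 0.90), young 1 h 2 (0.79), old sham 1 or 3 (0.78 and 0.88) or old 1 h 1 (0.87), with no low-count filter (0.94) or with the trend removed (0.41). Camera called these 4 lists with adjusted p = 0.00128, 0.000411, 0.000581 and 0.000581, and adjusted p = 0.99 for each with an estimated correlation. Il6 (0.32 ± 1.06, adjusted p = 0.888) and Cxcl1 (-0.28 ± 0.94, adjusted p = 0.89) did not pass. Il6 was at -0.25 with the trend removed and -9e-04 without old sham 4, and Cxcl1 at 0.0345 without young 1 h 3 and 0.135 without old sham 2. In all, 1588 genes were higher and 1863 lower. Of these, 821 were shared with the 1112 genes called with the GC trend removed.

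At 1 day the same interaction was tested. Cell cycle genes were lower in 19 of 24 cases (20 adjusted over the list alone, 18 with the GC trend removed; 12 without young 1 day 3, old sham 3, old 1 day 2 or old 1 day 4). Plk1 was at -2.16 ± 0.45 (adjusted p = 0.00119, n = 4 per group), the mitotic regulator Cdc20 at -2.04 ± 0.40 and Mcm2 at -1.41 ± 0.31. Albumin differed by 8.50 ± 1.32 (9.12 without old sham 2 and 7.58 without old 1 day 3) and Gsg1l by -3.57 ± 0.58 (-4.63 without old 1 day 1). Glucocorticoid-induced genes were higher in 11 of 13 (13 and 8; 7 without young sham 1, young sham 2 or old 1 day 2), with Sgk1 at 1.55 ± 0.33 and Klf9 at 1.16 ± 0.26. p53 targets were higher in 9 of 16 (10 and 8), with Trp53inp1 at 1.98 ± 0.31 and Pmaip1 at 1.42 ± 0.34, and oxidative phosphorylation genes were lower in 15 of 21 (15 lower and 1 higher over the list alone, 14 lower with the trend removed), with Cox4i1 at -0.97 ± 0.13 and Ndufa2 at -1.20 ± 0.18. Endothelial activation genes were higher in 5 of 18 by each count. The plasminogen activator Plat was at 1.41 ± 0.24 and Adamts4 at 2.80 ± 0.82 (2.16 without old 1 day 2). Endothelial activation genes numbered 3 without young sham 4, young 1 day 1 or old sham 1. Neutrophil markers were higher in 5 of 18 (5 and 4). Mmp8 was at 3.44 ± 0.85. Neutrophil markers numbered 3 without young sham 1, young 1 day 3 or old sham 1, 3 or 4, 8 without old 1 day 1 and 2 without old 1 day 2. Inflammatory genes were higher in 4 of 27 (2 and 2). Csf3 was at 4.63 ± 1.08 (3.73 without old 1 day 3) and Socs3 at 2.37 ± 0.65 (1.64 without old 1 day 2). Inflammatory genes numbered 2 without young 1 day 3, old sham 1, old sham 4 or old 1 day 3 and 7 without old 1 day 1.

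Type 2 markers were lower at the 1 day interaction in 6 of 16 cases (8 adjusted over the list alone, 2 with the GC trend removed). Sftpc was at -0.96 ± 0.25 and -0.68 (adjusted p = 0.0601) with the trend removed. B cell markers were lower in 6 of 13 (9 and 3; 3 without young sham 1, young 1 day 4, old sham 2, old sham 4 or old 1 day 4). Fcmr was at -2.03 ± 0.52 and Cd79b at -1.83 ± 0.48. MHC class II genes were lower in 6 of 10 (8 and 2). The class II transactivator Ciita was at -1.49 ± 0.41 and H2-Ab1 at -1.05 ± 0.27 and -0.70 (adjusted p = 0.064) with the trend removed. Class II genes numbered 3 without young sham 1, 2 or 4, young 1 day 1 or 4, old sham 1 or old 1 day 2, 3 or 4, and 10 without old 1 day 1. NRF2 targets were higher in 4 of 15 (4 over the list alone, 5 higher and 1 lower with the trend removed; 2 without young sham 1, young 1 day 4, old sham 1, old sham 4 or old 1 day 3). Mt2 was at 2.18 ± 0.60 and the glutathione synthesis gene Gclc at 1.16 ± 0.30. Camera called the cell cycle, glucocorticoid, p53, oxidative phosphorylation, endothelial activation, neutrophil, inflammatory, type 2, B cell, MHC class II and NRF2 lists with adjusted p = 1.12e-07, 4.67e-05, 0.00645, 9.24e-07, 0.0088, 0.0221, 0.0479, 0.00584, 0.00055, 0.00379 and 0.0479, and adjusted p = 0.959, 0.959, 0.959, 0.959, 0.959, 0.984, 0.984, 0.984, 0.959, 0.959 and 0.984 with an estimated correlation. None of them stayed called.

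Il6 differed between ages in its 1 day change by 3.36 ± 1.13 (adjusted p = 0.0306), but not past the threshold with the GC trend removed (2.72, adjusted p = 0.0928), nor without young sham 4 (3.23), young 1 day 3 or 4 (3.03 and 3.35), old sham 1 or 4 (3.21 and 3.04) or old 1 day 2 or 3 (2.93 and 2.80). Cxcl1 differed by 2.83 ± 0.98 (adjusted p = 0.0342), but not past the threshold with the trend removed (2.59, adjusted p = 0.0665), nor without young sham 2 or 4 (2.76 and 2.75), young 1 day 2, 3 or 4 (2.80, 2.65 and 2.92), old sham 1 or 4 (2.71 and 2.54) or old 1 day 3 (1.35). Neither gene passed with no low-count filter, when fitted with these groups alone or in limma. In all, 2990 genes were higher and 2984 lower at this interaction, with rho -0.5088 with GC content, and 4025 genes were called with the trend removed, 3141 of them shared. Lists in which no comparison was called were alveolar macrophage markers, club and secretory airway markers, interferon-stimulated genes, circadian clock genes, and skeletal muscle, fat and mesothelial genes. Among these, alveolar macrophage markers rose in 4 of 15 and fell in 4 in old 1 day lungs by either adjustment (adjusted p = 0.587), with a median of -0.10, a mean of 0.22 and a test pointing down. Circadian clock genes fell in 5 of 16 and rose in 1 in old 1 day lungs by either adjustment (adjusted p = 0.107). Tested as single transcripts, genes with at least 1 transcript past the threshold numbered 3326, 1123, 5582, 2122, 18, 3000, 4774, 436 and 1540 in the order of the 9 comparisons above. Between sham groups, 1269 genes passed when those groups were fitted alone and 871 in DESeq2.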

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

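Of the tests in this part, those chosen after the result was seen are the removal of the GC trend, the correlations across mitochondrial mRNAs, the B cell marker test and the splits of the samples, except the splits for the difference between ages at 1 day. Leaving out single libraries for cell cycle genes and those splits were planned.

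A single library stood apart from the other 3 of its group in 20 of 451 groups of values tested (Dixon's ratio). Chance marks about 1 in 20 groups, which would be 22.6. Over all genes, the chi-square per gene between replicates was 66.8 to 72.0 for pairs with old 1 h 1 and 23.5 to 33.6 for the other old 1 h pairs, and 93.7 to 144.7 for pairs with old 1 day 1 against 70.8 to 88.2. Without old 1 day 1 the difference between ages at 1 day was called for 6706 genes instead of 5974. In old 1 day 1, Actc1 was at 62.69 CPM (others 7.776 to 11.24), H2-Eb1 at 443.8 (234.1 to 247.1) and Mcm5 at 40.4 (13.55 to 17.42). Ngp was at 731.6 CPM in old 1 day 2 (12.01 to 39.44) and Cxcl5 at 78.24 in old 1 day 3 (8.57 to 14.21). In old 1 h 1, Ighg2c was at 1499 CPM (33.86 to 219.4) and Itga2b at 57.06 (41.3 to 42.77), and Icos was at 7.717 in old 1 h 4 (12.74 to 13.75). In old sham 2, Hdc was at 121.4 CPM (86.66 to 90.14), Igfbp7 at 381.8 (328.5 to 329.2), Saa1 at 0.1653 (0 in the others) and Wnt10b at 21.57 (28.57 to 29.2). Actc1 was at 492.9 CPM in old sham 4 (107.2 to 124.9). In young lungs, Sftpc was at 12350 CPM in young 1 day 1 (8396 to 9041), Upk3b at 7.724 in young 1 day 2 (1.616 to 2.361), ND6 at 9.604 in young 1 day 3 (1.823 to 2.539) and Plaur at 296.8 in young 1 h 1 (234.6 to 243.7). In young sham 3, ATP8 was at 460.8 (376.5 to 384.6) and Klf9 at 339 CPM (400.2 to 404). The mitochondrial share was 3.2066% in old sham 3, against 3.9773% to 4.0702% in the other old sham libraries.

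A difference between ages in the change from sham, tested as an interaction, was the other reason for a closer look. At 1 h it was past the threshold for 3451 genes. Lists called had medians of -0.62 (type 1 markers), -0.55 (endothelial markers), 0.75 (T and NK cell markers) and -0.38 (oxidative phosphorylation genes). None stayed called with an estimated correlation (adjusted p = 0.99 for each), and with the GC trend removed 2, 1, 2 and 8 members passed in that order. Single genes past the threshold were ATP8 (2.95), ND3 (2.26), ND6 (3.57), Cd28 (1.72), Il7r (0.93), Aqp5 (-0.90), Cldn18 (-0.67), Spock2 (-0.84), Cldn5 (-0.90), Tie1 (-0.85), Cox4i1 (-0.72), Ndufa2 (-1.07), Matn4 (-1.42) and Ddit3 (-0.66). Ddit3 did not pass without any library of these groups except young 1 h 2, young 1 h 3 and old sham 1 (-0.68 to -0.51), and Il7r lost its call without the libraries given in the report.

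At 1 day the difference between ages was past the threshold for 5974 genes. Lists called had medians of 0.84 (inflammatory genes), 0.785 (endothelial activation), 1.64 (neutrophil markers), 0.45 (NRF2 targets), 0.45 (p53 targets), 1.55 (glucocorticoid-induced genes), -0.68 (type 2 markers), -1.33 (B cell markers), -0.91 (MHC class II), -1.65 (cell cycle genes) and -0.56 (oxidative phosphorylation genes). None stayed called with an estimated correlation (adjusted p = 0.959 to 0.984). Higher in old by this test were Ngp (9.02), Alb (8.50), Csf3 (4.63), Saa1 (4.43), ND6 (3.68), Mmp8 (3.44), Il6 (3.36), Cxcl1 (2.83), Adamts4 (2.80), Socs3 (2.37), Mt2 (2.18), Trp53inp1 (1.98), Lcn2 (1.88), Il7r (1.76), Sgk1 (1.55), F3 (1.51), Cd28 (1.49), Pmaip1 (1.42), Plat (1.41), Gclc (1.16) and Klf9 (1.16). Lower were Gsg1l (-3.57), Plk1 (-2.16), Cdc20 (-2.04), Fcmr (-2.03), Cd79b (-1.83), Mcm5 (-1.66), Sdf2l1 (-1.62), Ciita (-1.49), Mcm2 (-1.41), Spib (-1.34), Cyp2f2 (-1.33), Colq (-1.31), H2-Ob (-1.29), Ndufa2 (-1.20), H2-Ab1 (-1.05), Cox4i1 (-0.97), Sftpc (-0.96), Tppp3 (-0.91), Sftpb (-0.89), Fasn (-0.85) and Cd68 (-0.82). Saa1 was at 8.00 without old sham 2, a fitted value against a group at 0, and Alb at 9.12 without that library and 7.58 without old 1 day 3. Ngp was at 6.13, Socs3 at 1.64 and Adamts4 at 2.16 without old 1 day 2, Csf3 at 3.73 and Cxcl1 at 1.35 without old 1 day 3, Gsg1l at -4.63 without old 1 day 1 and ND6 at 4.59 without young 1 day 3. Lcn2 did not pass without young sham 1 or 2 (1.71 and 1.78), old sham 1 or 4 (1.73 and 1.73) or old 1 day 2 or 4 (1.47 and 1.71). Cyp2f2 did not pass without young sham 2 (-1.26), young 1 day 2 (-1.20), old sham 1 or 4 (-1.18 and -1.23) or old 1 day 4 (-1.22), and Fasn not without young sham 4 (-0.70), young 1 day 1 or 4 (-0.83 and -0.82), old sham 2 or 4 (-0.80 and -0.77) or old 1 day 2 or 3 (-0.79 and -0.76). Il6 and Cxcl1 lost their calls without the libraries given in the report.

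Other splits were tried for each gene count. For the 7 comparisons of 2 groups, 1 of 35 splits, the real one, gave as many genes, the lowest share possible. Chance is less likely but not excluded. The real counts and the highest of the other splits were 8138 and 76 (young 1 h), 4962 and 2 (old 1 h), 10616 and 0 (young 1 day), 7156 and 1066 (old 1 day), 454 and 2 (sham), 8265 and 77 (ages at 1 h) and 9892 and 3205 (ages at 1 day). For the difference between ages at 1 h, 5 of 100 splits gave as many genes (real 3451, highest other 5608), and at 1 day 4 of 100 did (real 5974, highest other 7024). Splits that mixed old and young reperfused libraries called at most 1 gene at 1 h and 99 at 1 day. Mixing puts the difference between ages in reperfused lungs into the spread within groups. Few calls would follow with or without an interaction, so these splits cannot exclude chance. At each time 4 other splits drawn kept those libraries apart as the real one does and mixed the shams, and they called 4246 to 5608 genes at 1 h and 5796 to 7024 at 1 day. The counts thus follow the separation of the reperfused libraries by age. They do not exclude chance for either interaction, nor in how the shams are grouped.

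The first pattern weighed is the difference between ages at 1 h, in which 3451 genes passed. With each library's GC trend removed, 1112 genes were called, against 529 between sham groups with the same correction, which argues against that trend as the whole cause. A GC-dependent recovery of RNA in the young 1 h libraries may cause part of it: over the 13 mitochondrial mRNAs, which the trend was not fitted on, rho of GC content with the young 1 h change was 0.7637 (permutation p = 0.00338). A length-dependent recovery cannot be told apart, since rho with transcript length over the same mRNAs was 0.467 (permutation p = 0.111). Age stays open as untested, as does an unrecorded batch. The labels give no batch, and the young 1 h and young 1 day libraries differ from the other 16 in the GC trend.

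The second pattern is the lower level of cell cycle genes in old than in young 1 day lungs, 24 of 24. With the GC trend removed 24 were still lower, which argues against the trend as the whole cause. The lowest number with 1 library left out was 20, which argues against a single library. As an interaction 19 were lower, 18 with the trend removed and 12 without young 1 day 3, old sham 3, old 1 day 2 or old 1 day 4. A weaker proliferative response in old lungs may underlie it, a hypothesis these data raised. Cell composition, timing and an unrecorded batch stay open, with age untested.

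The third pattern is the higher level of neutrophil markers in old than in young 1 day lungs, 14 of 18 and 9 without old 1 day 2. With the GC trend removed 13 were higher, which argues against the trend as the whole cause. More blood left in the old 1 day lungs would raise blood cells together, but 13 of 13 B cell markers fell against old sham, Cd79a from 79.2 to 28.1 CPM and Cd79b from 70.3 to 19.9 CPM, while S100a8 was at 652 against 196 CPM, which argues against more blood alone, while red cell and platelet genes, higher in old in 4 of 11 cases at 1 day, were so in 4 of 11 between sham lungs and rose in 1 of 11 in old 1 day against old sham. As an interaction 5 neutrophil markers were higher, 4 with the trend removed, 3 without young sham 1, young 1 day 3 or old sham 1, 3 or 4, 8 without old 1 day 1 and 2 without old 1 day 2. Age, batch and a fall of B cells by itself stay open as untested. So does a difference from before clamping, as the list was called higher between sham lungs (median 0.57, adjusted p = 0.0201, and 0.831 with an estimated correlation).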

How the results depend on the processing

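Of the tests in this part, the removal of the GC trend and of the GC and length trends were chosen after the result was seen.

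The text names 260 log2 changes or differences, of which 247 were called. Under 8 alternatives named in advance that keep every library compared, single transcripts left out, 240 kept direction and side of the threshold in each. The other 20 changed in at least 1. Over the 2080 values of these alternatives 34 lost the call, 11 gained it and 5 reversed. With the GC trend or the GC and length trends removed, 241 kept both, 31 of 520 values lost the call, 2 gained it and 2 reversed. With 1 library left out (24 in turn), 235 kept both, 97 of 2544 values lost the call, 2 gained it and 6 reversed. DESeq2 size factors left 259 of 260 as they were and a filter of at least 1 CPM in 4 libraries all 260. Genes whose call ended in the report's comparisons are named there. Among the differences between ages given in this closing section alone, Spock2 (-0.59), Colq (-0.97), Cyp2f2 (-1.09), Fasn (-0.50) and Sftpb (-0.53) did not pass with the GC trend removed, nor Ddit3 (-0.80) and Cd68 (-0.52) with GC and length removed. Ddit3 did not pass either with DESeq2 size factors (-0.63), no low-count filter (-0.64) or in limma (-0.59 and -0.60), Lcn2 with no low-count filter (1.86), Cyp2f2 with these groups alone (-1.34), Colq in limma on log2(TPM + 1) (-0.70) and Fasn in limma (-0.71 on both scales). The cause was not tested.

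Counts of genes were within 1.5-fold of the reported count under the alternatives, with these exceptions. Tested as single transcripts, genes with at least 1 transcript past the threshold numbered 3326 (young 1 h), 1123 (old 1 h), 5582 (young 1 day), 2122 (old 1 day), 18 (sham), 3000 (ages at 1 h), 4774 (ages at 1 day), 436 (difference between ages at 1 h) and 1540 (at 1 day). By construction the reads of a gene with more than 1 transcript are divided among them. Between sham groups 1269 genes passed when these groups were fitted alone and 871 in DESeq2, and the cause was not tested. For the difference between ages at 1 h, 1112 genes passed with the GC trend removed and 1147 with GC and length removed. At 1 day 3845 passed with GC and length removed. By construction the correction takes out the part of a difference that follows GC content or length. Over all 9 comparisons 107 lists were called by camera and 4 with an estimated correlation, which allows for the correlation among members measured in these libraries.

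Leaving out 1 library gave 7009 to 7902 genes (young 1 h), 3766 to 4681 (old 1 h), 9535 to 10554 (young 1 day), 5887 to 7289 (old 1 day), 225 to 379 (sham), 7428 to 7693 (ages at 1 h), 8841 to 9959 (ages at 1 day), 2493 to 3335 (difference at 1 h) and 4959 to 6706 (difference at 1 day), and 99 to 109 lists. The sham count was more than 1.5-fold lower without young sham 1, 2 or 4 or old sham 1 or 3 (225, 233, 261, 271 and 259). Groups of 3 have fewer samples, which lowers most of these counts.

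Reversed values were all of Il6 and Cxcl1 where neither was called, and the cause was not tested. Il6 in old 1 day against old sham (0.55) was at -0.34 in limma on log2(TPM + 1) and -0.41 on log2(TPM + 0.1), and -0.034 to 1.11 with 1 library left out. Il6 for the difference between ages at 1 h (0.32) was at -0.25 with the GC trend removed and -0.24 with GC and length removed, and -9e-04 to 0.905 with 1 library left out. Cxcl1 for the same difference (-0.28) was at 0.1975 and 0.1981 in limma on log2(TPM + 1) and log2(TPM + 0.1), and -0.58 to 0.135 with 1 library left out. With 1 library left out, Cxcl1 in old 1 day against old sham (1.36) ran from -0.13 to 1.76, and Il6 between sham groups (0.56) from -0.013 to 0.89.

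Replicate numbers do not pair the samples: centred profiles of the same number correlated between groups by -0.3546 to 0.2157. With the replicate number as a block the counts were 8036, 4842, 10542, 6983, 407, 8223, 9724, 3439 and 5860 in the order above, and Cxcl1 for the difference between ages at 1 h was at 0.0089, a reversal whose cause was not tested. Calls that ended with the block were Cxcl1 in young 1 h (1.63), Cdkn2a in young 1 day (1.25), C4b (0.84) and Col4a3 (-0.66) between sham groups, and Cxcl1 for the difference between ages at 1 day (2.58). Il6 in old 1 h passed (2.29).

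Limma on TPM changes the scaling, the measure and the test together. The median of all genes was -0.17 in young 1 h, -0.12 in old 1 h and -0.15 in young 1 day against sham on log2(TPM + 1), and -0.25, -0.16 and -0.24 on log2(TPM + 0.1), where it was 0.12 between ages at 1 day and 0.10 and 0.12 for the differences at 1 h and 1 day. Of the genes called, the share that was higher went from 51.36% to 22.88% (young 1 h), 49.88% to 25.49% (old 1 h), 51.78% to 34.93% (young 1 day), 55.13% to 44.75% (old 1 day), 46.02% to 64.70% (difference at 1 h) and 50.05% to 67.01% (at 1 day) on log2(TPM + 1). On log2(TPM + 0.1) it was 22.67%, 24.39%, 34.33%, 44.52%, 64.32% and 67.27%. With the GC trend removed it was 39.33% in old 1 h and 33.27% for the difference at 1 h. Genes higher and lower by more than 2-fold, in the order of the 9 comparisons, numbered 381 and 843, 494 and 188, 666 and 1450, 525 and 772, 78 and 79, 795 and 137, 967 and 486, 317 and 35, and 884 and 308 on log2(TPM + 1). On log2(TPM + 0.1) they numbered 593 and 1954, 707 and 663, 976 and 2809, 775 and 1532, 140 and 123, 1506 and 319, 1874 and 910, 545 and 76, and 1413 and 494. With all libraries in edgeR those not given in the report were 378 and 131 (difference at 1 h) and 986 and 757 (at 1 day). DESeq2 size factors, which change the scaling alone, gave shares of 49.02%, 51.68%, 49.37%, 49.49%, 45.09%, 51.36%, 48.75%, 52.32% and 49.26% in the order of the 9 comparisons, so the majority turned in all of them but sham. Which part of the TPM alternatives moved the shares and these counts was not tested.

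Depth and 4 libraries per group limit what can be seen. In simulated data 44% to 74% of 2-fold changes were recovered.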
